A study of Aspergillus fumigatus with 3 samples.

How the data were processed

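The series compared sporulating cultures of the mould Aspergillus fumigatus, strain ATCC 34506, at 17 and 32 °C. Per the labels' protocols, mycelium from an overnight liquid culture at 37 °C was divided onto potato dextrose agar plates, and both sets of plates were incubated for 48 h before harvest with a swab. RNA from the plates was turned into aminoallyl cDNA, coupled to the dyes Cy3 and Cy5, and hybridised so that each array held both temperatures. The labels name 3 biological replicates from separate experiments. Each replicate was hybridised on 2 arrays with the dyes swapped, which gives 6 arrays. The p-values therefore measure the spread between 3 divided cultures.

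Per the file headers, the authors quantified the scans with TIGR Spotfinder 3.2.1, using Otsu segmentation, spot sizes from 3 to 100, a quality filter and background correction. The deposited array files hold background-corrected integrated spot intensities on a linear scale, with 0 where a channel did not pass the authors' filter. Per the file headers, a spot also had to exceed the median background by 1 background SD. The direction of every ratio was taken from the line in each file header that names the channel of each temperature. A deposited value table holds 1 value per spot and replicate, read here as a log ratio, with column medians of 0.0529, -0.00677 and 0.0198 for replicates 1, 2 and 3. These values correlated with the log2 ratios computed here across spots at r = 0.961, 0.964 and 0.927 for replicates 1, 2 and 3, in the direction 17 over 32 °C, with slopes of 0.879, 0.904 and 0.739. How the authors normalized that table, and why its slopes lie below 1, stays unknown, as does its log base, which was taken as 2. It served as an alternative.

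Each array has 22176 spots, of which 17914 carry 1 of 8947 genes in the probe table and 4262 are not listed there. Of the gene entries, 8879 were matched to the RefSeq table of assembly ASM265v1, which was used for names and gene order, and 68 were not. The genome build behind the probes is not given in the sources used here, so no coordinates are printed. The files name genes by symbol or locus tag, with no description of the product.

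The gene of a spot was assigned after a correction chosen after seeing the data. When the probe number was read as the spot number, as deposited, duplicate spots correlated at r = 0.0175 to 0.0996 on single arrays. When positions were counted down the columns of each print block, the 11088 duplicate pairs correlated at r = 0.924 to 0.963. Probes with a listed gene were then measured on 49.7% of array positions and probes without one on 29.2%, against 43.6% and 43.3% under the deposited numbering. The share for probes without a gene leaves out 2016 positions listed in almost no print block, taken here as control or empty positions. These control positions were measured in 3.22% of cases, against 42.0%. Log2 ratios of neighbouring genes correlated at r = 0.122 across 5979 pairs, against 0.00288 under the deposited numbering and at most 0.0484 after shuffling. Counting down the columns with the print blocks in 4 other orders gave the same correlation of duplicates and the same value at control positions, so these do not settle the order of the blocks. That order rests on the other 2 values. In those 4 orders unlisted probes were measured on 38.8% to 41.7% of positions, and neighbouring genes correlated at r = -0.0109 to 0.0148. Of 14526 spots with a gene under both numberings, 14426 changed gene. Every gene named in the text rests on this correction.

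Spots with both channels above 0 and a listed gene were normalized within each array by global loess (span 0.3, 4 iterations) of log2 Cy5 over Cy3 against mean log2 intensity. The spots of a gene were averaged, the sign was turned so that values are log2 of 17 over 32 °C, and the swapped arrays of a replicate were averaged into 1 value. A gene was tested where all 6 arrays measured it. Tests used lmFit and eBayes in limma 3.58.1 under R 4.3.3 (statmod 1.5.0), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Because 1 array measured few spots, a larger set of genes with at least 1 array in each replicate was also tested, a choice made after seeing the data. A gene measured on 1 array of a replicate keeps that array's dye effect. Over the 1757 genes on all 6 arrays this effect had an SD of 0.17 on the log2 scale and exceeded 0.5 for 1.08% of them. It was not measured for genes that lack an array, and may differ there. Saturated spots were kept at their values.

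Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, where at least 5 genes of a list were tested, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The design, the alternatives, 36 lists and the rule for named genes were fixed before the data were examined. Of the 36 lists, 15 rested on words of product descriptions and matched no gene, and 6 reached 5 tested genes. A further 24 lists by gene symbol were written once the files' symbols were known, before any gene's value was seen. They are called added lists, and 13 of them reached 5 tested genes. Adjusted p of planned and added lists were computed separately. The named genes are the 12 largest changes in each direction among genes with a symbol and 1 sign in all replicates, the 2 largest without a symbol in each direction, the 3 members of each tested list with the lowest p, and every tested allergen gene. Other list members are named as examples chosen after their values were seen.

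The test was checked on simulated data with the 1757 genes, of which 50 each were changed by 1.5, 2, 3 and 4-fold. It recovered 48% of the 1.5-fold, 78% of the 2-fold, 96% of the 3-fold and 96% of the 4-fold changes, and 8 of its 167 calls were false. Camera put 0 of 100 unchanged lists past 0.05. The simulated genes varied independently, so this does not check camera on lists whose genes vary together. Nor does it check the share of false calls in the gene test where genes vary together. Among the lists tested on all 6 arrays, the estimated correlation ran from -0.107 for drug efflux to 0.868 for conidiation regulators. The ratio within an array pairs both plates of a divided culture, so the main test keeps the replicate block. A test of the channels as 3 against 3 separate samples, with no replicate block, called 136 genes. The other alternatives changed the normalization, background correction, filters, arrays used, test and replicates. A setting with no filter on the authors' quality calls could not be run, because spots that failed hold 0.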

Results

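Gene expression of sporulating A. fumigatus was compared at 2 growth temperatures. A. fumigatus is an airborne mould whose conidia carry many allergens, and the comparison asked how the transcriptome of a sporulating culture differs between 17 and 32 °C. There was 1 group of 3 biological replicates, each a ratio of 17 over 32 °C from 2 dye-swapped arrays. The arrays of replicate 1 measured 10782 spots in both channels with the 17 °C sample in Cy3 and 7861 with it in Cy5. The arrays of replicate 2 measured 12374 and 12086 spots, and those of replicate 3 measured 10948 and 3724, in the same order. On that last array the Cy3 channel, which held the 32 °C sample, passed the quality filter at 3748 spots and the Cy5 channel at 11909. Log2 ratios of the 1757 genes measured on all 6 arrays correlated across genes at r = 0.788, 0.812 and 0.846 between pairs of replicates. Genes are not independent replicates, and the number of arrays limits the precision of each value. Values below are mean log2 ratios of 17 over 32 °C ± SD (n = 3), so that positive values are higher at 17 °C, and p-values are limma's, adjusted over all genes tested.

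Of the fumagillin and pseurotin cluster genes measured on all 6 arrays, 15 of 16 were higher at 17 °C than at 32 °C. On an added list of wall synthases and transglycosidases 10 of 14 were lower. In the larger set these counts were 18 of 19 and 12 of 22. Neither list passed a set test with an estimated correlation between genes (adjusted p = 0.376 and 0.643). Of the 1757 genes, 631 differed at an adjusted p under 0.05, with 301 higher and 330 lower at 17 °C. The highest gene with a symbol was fmpA, of the fumipyrrole cluster, at 3.68 ± 0.84 (12.8-fold, adjusted p = 0.000141), with saturated spots on 1 array. The lowest was egl3, which encodes an endoglucanase, at -3.58 ± 0.30 (adjusted p = 2.45e-05), with saturated spots on 2 arrays. Because saturated spots were kept at their values, log2 ratios and folds of genes with such spots are not exact, and the order of the largest changes is uncertain. Changes of more than 2-fold were found for 73 higher and 124 lower genes, and the median size among called genes was 0.74.

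Further genes at the upper end were alcC, an alcohol dehydrogenase gene (2.82 ± 0.64), grg1, a homologue of a glucose-repressible gene (2.32 ± 0.46), and dprB, which encodes a dehydrin-like protein (2.26 ± 0.82). The gene crmC stood at 2.12 ± 1.07, pldA, which encodes a phospholipase D, at 1.98 ± 0.56, and srbB, a transcription factor of the hypoxia response, at 1.71 ± 0.59. At the lower end were mp2, which encodes a relative of the antigenic mannoprotein Mp1 (-3.31 ± 0.44), CweA (-2.57 ± 1.75) and mfsC, a transporter of the major facilitator superfamily (-1.99 ± 0.43). Without a symbol, AFUA_4G01360 (3.17 ± 1.08) and AFUA_1G15270 (2.88 ± 0.27) were highest, and AFUA_8G06560 (-3.49 ± 0.91) and AFUA_1G10150 (-3.32 ± 1.48) were lowest. Spots of alcC were saturated on 4 arrays, those of grg1 and CweA on 5, those of AFUA_1G15270 on 4 and those of mp2 on 1. CweA stood at -1.62 without replicate 1. In the larger set of 4945 genes, with at least 1 array in each replicate, 1138 differed, 545 higher and 593 lower, and 567 of the 631 genes were called in both sets, all in the same direction. Without replicate 2, 400 of the 1757 genes were called, and without any normalization 623 were, split into 381 higher and 242 lower as the median of all genes shifted to 0.10. An ordinary one-sample test on the same values called 1 gene, AFUA_1G02550, and 508 genes at an unadjusted p under 0.05.

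Genes for fumagillin and pseurotin, made from intertwined clusters near the start of chromosome 8, rose at 17 °C almost without exception. Of the 16 tested members, 15 rose over all genes tested and 15 when adjusted over the list alone, and the list's median was 1.41 (camera adjusted p = 2.71e-11). With an estimated correlation between genes the list had adjusted p = 0.376, and fry gave adjusted p = 0.0233. Examples are AFUA_8G00400 (2.42 ± 0.27, 5.37-fold), fmaD, a methyltransferase gene of fumagillin synthesis (1.96 ± 0.29), fma-TC, its terpene cyclase gene (1.85 ± 0.63), and psoC, a methyltransferase gene of pseurotin synthesis (1.81 ± 0.16). The pseurotin gene psoE stood at 1.64 ± 0.12, with saturated spots on 3 arrays. The remaining member, fpaI, stood at 0.10. Of the 19 members in the larger set, 18 rose. That set added fumR, the regulator of the cluster, at 0.97, a call that ended without replicate 2 (0.58, adjusted p = 0.0862). It also added fmaE at 0.56, which then had adjusted p = 0.163.

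The neighbouring fumitremorgin genes, for a prenylated indole alkaloid, were measured mainly in the larger set. Of the 6 members tested in the larger set 5 rose, over all genes tested and adjusted over the list alone, with a median of 1.61 (camera adjusted p = 0.000184). This was adjusted p = 0.329 with an estimated correlation. The peptide synthetase gene ftmA stood at 1.80 ± 0.49, ftmD at 1.75 ± 0.34 and ftmF at 1.47 ± 0.14. The exception was ftmE at 0.06. On all 6 arrays, 2 members were measured and 1 rose.

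**Figure D1:**
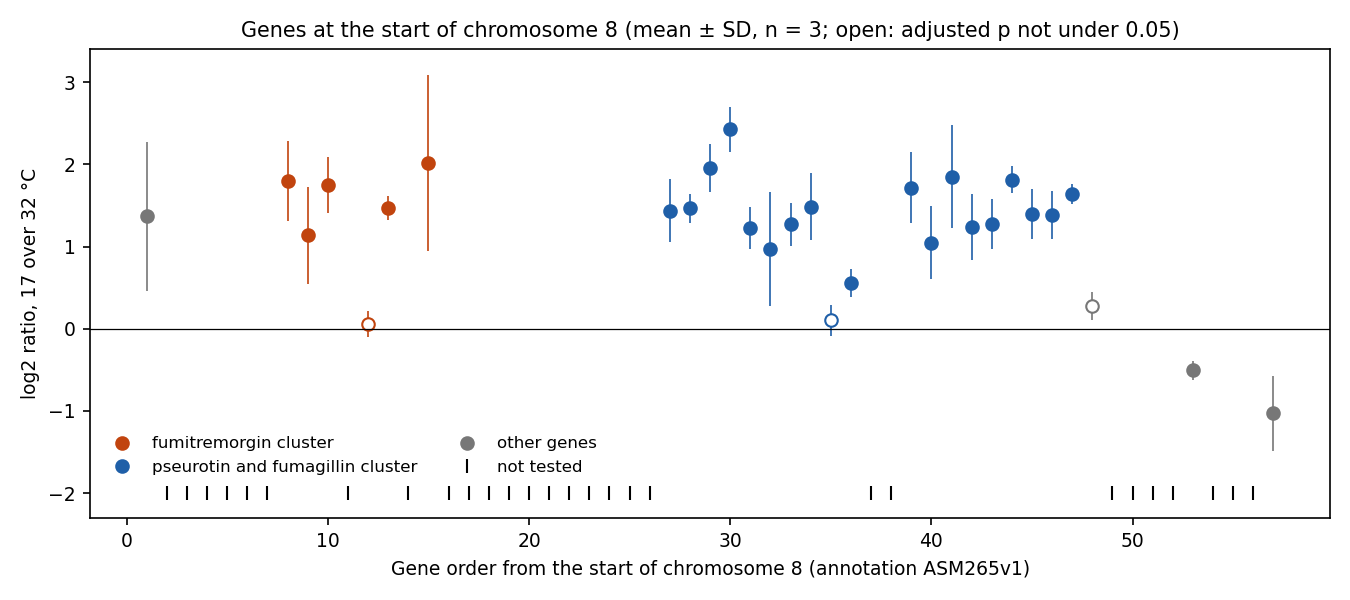
Log2 ratio of 17 over 32 °C (y axis, mean ± SD, n = 3) of genes at the start of chromosome 8, in the gene order of assembly ASM265v1 (x axis), for genes with at least 1 array in each replicate. Filled points passed an adjusted p under 0.05 and ticks mark genes not tested. Of the pseurotin and fumagillin cluster, 18 of 19 genes lie above 0 and past the threshold, as do 5 of 6 fumitremorgin genes.

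The clusters elsewhere in the genome moved in both directions. Fumipyrrole genes, an added list, had 6 of 7 members higher at 17 °C in the larger set, and 7 when adjusted over the list alone, with a median of 2.20 (camera adjusted p = 1.88e-06, and adjusted p = 0.563 with an estimated correlation). Beside fmpA, fmpB stood at 2.86 ± 0.77 and fmpF at 2.78 ± 0.49. Trypacidin genes, for a metabolite of conidia, had 4 of 6 members lower in the larger set (4 adjusted over the list alone), among them tpcC at -1.99 ± 0.78 and tpcF at -1.51 ± 0.23. Their median was -1.12 (camera adjusted p = 0.00297, and adjusted p = 0.329 with an estimated correlation). In the added list of hexadehydroastechrome genes, 4 of 5 members fell in the larger set, led by hasB at -3.35 ± 0.93 (10.2-fold lower). The list had camera adjusted p = 0.00641, and adjusted p = 0.683 with an estimated correlation. Without replicate 2, 2 of those 4 calls remained.

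Ergot alkaloid genes of the fumigaclavine cluster had 2 of 7 members lower in the larger set, and 3 adjusted over the list alone (camera adjusted p = 0.0634). Without replicate 2 the list passed (camera adjusted p = 0.00606), and its median of -0.19 became -0.41. The 2 were dmaW, which encodes the prenyltransferase of the first step (-1.90 ± 1.59), and fgaDH, a dehydrogenase gene of the pathway (-1.86 ± 1.01). Without replicate 1, dmaW stood at -1.03. Of gliotoxin genes 3 were tested in the larger set and 1 was higher, gliN at 0.62, a call that ended without replicate 2 (adjusted p = 0.11). None of 4 tested helvolic acid genes and none of 4 tested fumiquinazoline genes passed limma's threshold at an adjusted p under 0.05. Of the polyketide and peptide synthase genes listed across clusters, 4 of 7 were higher and 1 was lower in the larger set, with the same counts adjusted over the list alone (camera adjusted p = 0.0235). This became adjusted p = 0.329 with an estimated correlation and adjusted p = 0.0983 without replicate 2. The list overlaps clusters counted separately. Its higher genes include fma-PKS (1.43) and nrps14 (1.27) of the pseurotin and fumagillin cluster, and its lower gene is pksP of the DHN melanin cluster.

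**Figure D2:**
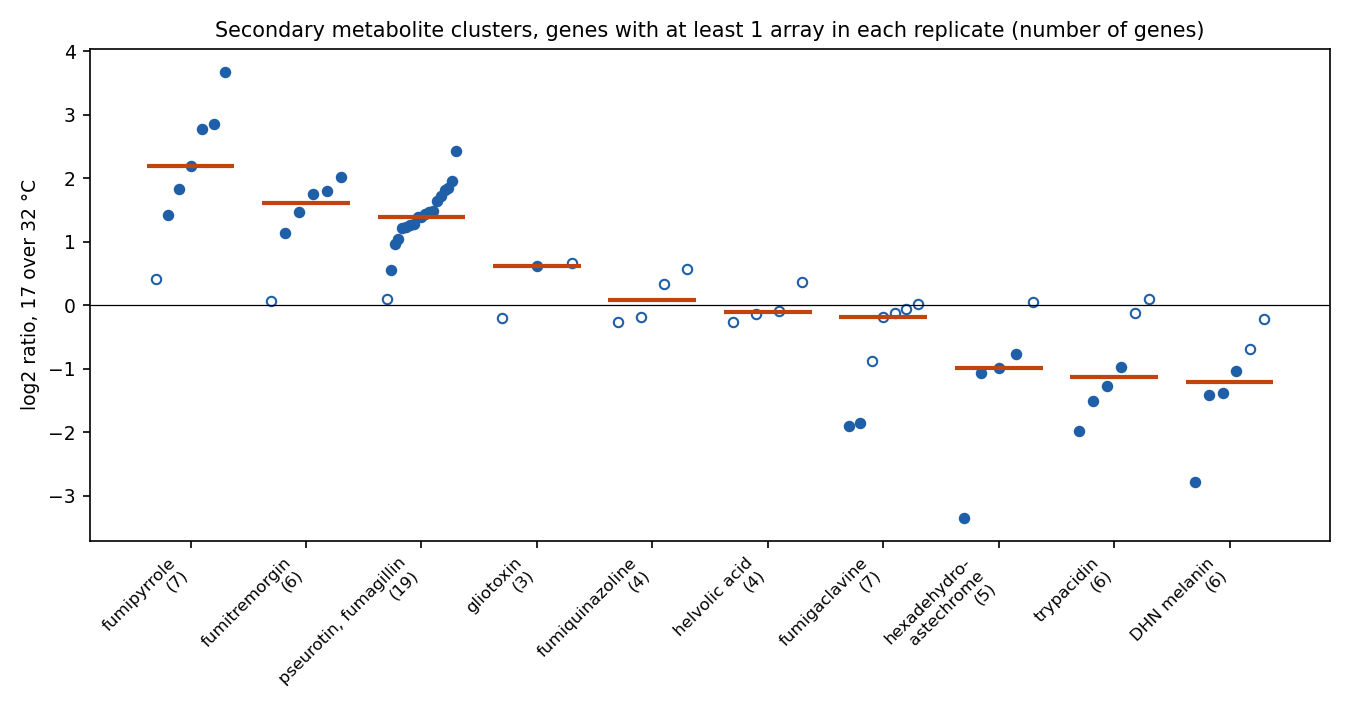
Log2 ratio of 17 over 32 °C (y axis) of each tested gene in 10 secondary metabolite clusters (x axis, number of genes in brackets), for genes with at least 1 array in each replicate. Points are means of 3 replicates, filled where the adjusted p is under 0.05, and lines are list medians. The medians run from 2.20 for fumipyrrole to -1.21 for DHN melanin, which without replicate 1 was -0.69, above trypacidin at -1.14 and hexadehydroastechrome at -1.17.

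Many, but not all, genes tied to conidia were lower at 17 °C. In the added list of conidium-associated genes, 9 of 15 tested members fell and 1 rose, with a median of -1.04 (camera adjusted p = 0.00851). The list had adjusted p = 0.672 with an estimated correlation, and without replicate 1 the median was -0.60. The hydrophobin gene rodC stood at -2.77 ± 1.22, cspA, which encodes a repeat-rich protein of the conidial wall, at -2.55 ± 0.71 with saturated spots on 3 arrays, and ccpA, which encodes a conidial cell wall protein, at -2.29 ± 1.19. The riser was dprB. The 6 tested conidiation regulators included 3 that fell, also adjusted over the list alone (camera adjusted p = 0.0339, fry adjusted p = 0.0538). Camera gave adjusted p = 0.512 with an estimated correlation, 0.0761 without replicate 1 and 0.0537 without replicate 3. They were wetA, which acts late in conidium maturation (-2.16 ± 0.43), medA (-0.69 ± 0.14) and vosA (-0.54 ± 0.44). The call of vosA, at adjusted p = 0.0485, ended without replicate 1 (0.0757) and without replicate 3 (0.178). The central activator of conidiation, brlA, was tested in the larger set and stood at -1.41 ± 0.40. In that set 4 of 11 regulators fell, and 6 adjusted over the list alone (camera adjusted p = 0.00768, fry adjusted p = 0.0347). With an estimated correlation camera gave adjusted p = 0.329 there.

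The cluster for DHN melanin, the pigment of the conidium, had 3 of 5 tested members lower, also adjusted over the list alone, and a median of -1.04 (camera adjusted p = 0.0241, fry adjusted p = 0.125). With an estimated correlation camera gave adjusted p = 0.512, and without replicate 1 the median was -0.60. The polyketide synthase gene pksP stood at -2.78 ± 0.73 (6.88-fold lower), abr2 at -1.38 ± 1.05 and ayg1 at -1.04 ± 0.86. Without replicate 1, abr2 stood at -0.78 and ayg1 at -0.60. The melanin genes, wetA and vosA also belong to the list of conidium-associated genes. The sole gene of the planned hydrophobin list, rodB, stood at 1.15 ± 1.29, with replicate values of -0.33, 1.73 and 2.04. Its mean was 1.88 without replicate 1 and 0.70 without replicate 3. It did not pass over all genes tested, and it passed adjusted over the list alone, which for 1 gene is the unadjusted p.

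Genes that build the cell wall were examined next. In the added list of wall synthases and transglycosidases, 10 of 14 tested members fell and none rose in limma's test over all genes, with a median of -0.75 (camera adjusted p = 0.00119, fry adjusted p = 0.0467). Of the 13 added lists tested on all 6 arrays, only this 1 passed with fry. With an estimated correlation the list had adjusted p = 0.643. In the larger set 12 of 22 members fell and 0 rose, with a median of -0.58. There the list had camera adjusted p = 0.000165, and adjusted p = 0.563 with an estimated correlation. Fry gave it adjusted p = 0.0245 in that set. Other added lists also passed with fry there: glycolysis and fermentation (adjusted p = 0.0372), peroxins (0.0238) and ergosterol by symbol (0.0238). The glucanosyltransferase gene gel3 stood at -1.73 ± 0.49 (3.32-fold lower), ags1, an alpha-1,3-glucan synthase gene, at -1.33 ± 0.49, and chsA, a chitin synthase gene, at -1.31 ± 0.30. The sole beta-1,3-glucan synthase gene on the list, fks1, stood at -0.15. The shorter planned list of gel genes had 4 of 6 members lower in the larger set, and 5 adjusted over the list alone (camera adjusted p = 0.00441). This became adjusted p = 0.329 with an estimated correlation, and 2 of the 4 calls remained without replicate 2.

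Allergen genes went both ways. Of 17 tested, 6 rose, 4 fell and 7 did not pass, and adjusted over the list alone 7 rose and 4 fell. The list's median of 0.32 did not stand apart from other genes (camera adjusted p = 0.253). The gene of Asp f 1, a ribotoxin that is a major allergen of the species, was higher at 17 °C at 0.98 ± 0.20 (adjusted p = 0.00159), with saturated spots on 4 arrays, so the size of this change is uncertain. Others that rose were pep1, an aspartic protease gene (1.85 ± 1.03), aspf3, a peroxiredoxin gene (1.23 ± 0.04), rpL3, a ribosomal protein gene (0.80 ± 0.36), hsp90 (0.64 ± 0.07) and aspf27, a cyclophilin gene (0.44 ± 0.22). The calls of rpL3 and aspf27 ended without replicate 2, at adjusted p = 0.0539 and 0.241. Those that fell were mp1, which encodes a cell wall mannoprotein (-2.19 ± 1.07), the gene listed as aspf13 (AFUA_2G12630, -1.47 ± 0.19), aspf34 (-1.16 ± 0.24) and aspf9, a wall transglycosidase gene (-0.87 ± 0.14). Whether the symbol aspf13 marks the allergen of that number at this locus is uncertain. Spots of pep1, rpL3 and aspf13 were saturated on 1 array each.

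Allergen genes that did not pass included aspf2 (0.03 ± 0.12, adjusted p = 0.886), whose spots were saturated on 4 arrays, and the protease gene alp2 (0.00 ± 0.40, adjusted p = 0.997). They also included cyp4 (0.41 ± 0.22), aspf29, a thioredoxin gene (0.35 ± 0.21), aspf7 (0.32 ± 0.30, saturated on 1 array), aspf22, the enolase gene (0.25 ± 0.23), and aspf4 (-0.17 ± 0.40). In the larger set sod3, a superoxide dismutase gene, was higher at 2.92 ± 1.54 (adjusted p = 0.00292) and alp1, which encodes a secreted alkaline protease, was lower at -1.28 ± 1.30 (adjusted p = 0.0468). Without replicate 1, alp1 stood at -0.61. In that set aspf8 stood at 0.17 ± 0.43, and aspf27 no longer passed (adjusted p = 0.058). The metalloprotease gene mep was measured on 2 arrays and was not tested.

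**Figure D3:**
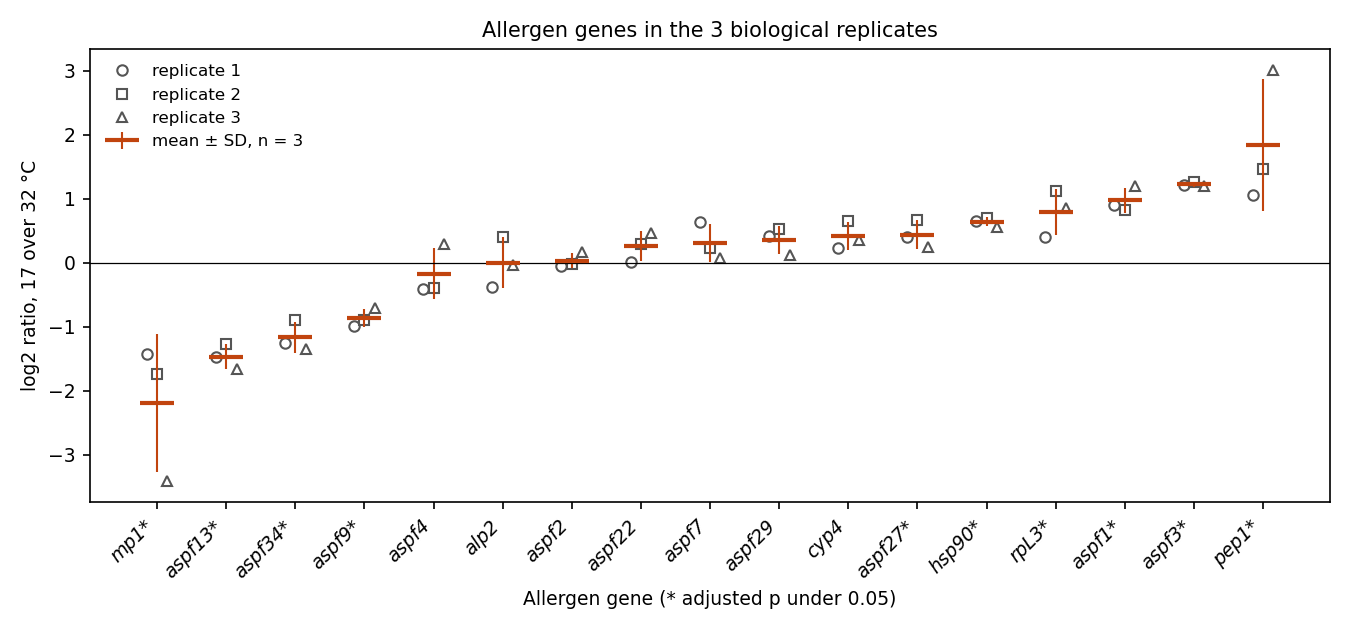
Log2 ratio of 17 over 32 °C (y axis) of the 17 allergen genes measured on all 6 arrays (x axis). Open symbols are the 3 biological replicates, lines with bars are mean ± SD, and asterisks mark an adjusted p under 0.05. The gene aspf1 lies above 0 in all 3 replicates and mp1 lies below 0 in all 3.

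Fermentation and glycolysis genes were mostly higher at 17 °C. In the added list, 6 of 7 tested members rose, with a median of 0.75 (camera adjusted p = 0.00119, and adjusted p = 0.643 with an estimated correlation). Besides alcC, the pyruvate decarboxylase gene pdcA stood at 1.42 ± 0.41 with saturated spots on all 6 arrays, and the phosphoglycerate kinase gene pgkA at 0.75 ± 0.07. Another alcohol dehydrogenase gene, adh1, went the other way in the larger set, at -1.67 ± 0.13. Among TCA cycle and respiration genes, 1 of 10 rose and 1 fell (camera adjusted p = 0.41). These were aox, which encodes the alternative oxidase (1.16 ± 0.54), and acuE, which encodes malate synthase of the glyoxylate cycle (-0.99 ± 0.06). The gene nde1 stood at -0.33 ± 0.07 (adjusted p = 0.0835).

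Parts of the chaperone, proteasome and translation lists rose, and many of these calls ended without replicate 2. Calls also ended without it over all genes, where 389 of the 631 were kept. Of the 5 planned heat shock genes, 4 rose, also adjusted over the list alone, with a median of 0.64 (camera adjusted p = 0.0101, fry adjusted p = 0.0233). With an estimated correlation the list had adjusted p = 0.376. They were hsp78 (0.95 ± 0.57), hsp70 (0.93 ± 0.11), hsp90 (0.64 ± 0.07) and hsp88 (0.60). Without replicate 2, hsp78 stood at 0.72 (adjusted p = 0.061) and hsp88 at 0.54 (adjusted p = 0.0678). In the wider added list of chaperones 5 of 11 rose, with a median of 0.43 (camera adjusted p = 0.00519, and adjusted p = 0.643 with an estimated correlation), which was 0.25 without replicate 2. Of those 5 calls, 2 remained without that replicate.

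Of 5 tested proteasome genes, 4 rose (camera adjusted p = 0.0167), among them pup3 (0.68 ± 0.30), rpt1 (0.55 ± 0.11) and pup1 (0.54 ± 0.08), which encode subunits of the complex. The list had adjusted p = 0.643 with an estimated correlation, and without replicate 3 camera gave adjusted p = 0.0866. Without replicate 2, 0 of the 4 calls remained. The genes pup3, rpt1 and pup1 then stood at 0.57, 0.51 and 0.54, with limma's adjusted p = 0.0754, 0.0832 and 0.0669. Of 12 translation genes 8 rose (camera adjusted p = 0.00216, and adjusted p = 0.672 with an estimated correlation), with rps23 (0.93 ± 0.32), rps1 (0.88 ± 0.35) and rpL3 highest. Without replicate 2, 2 of those 8 calls remained.

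**Figure D4:**
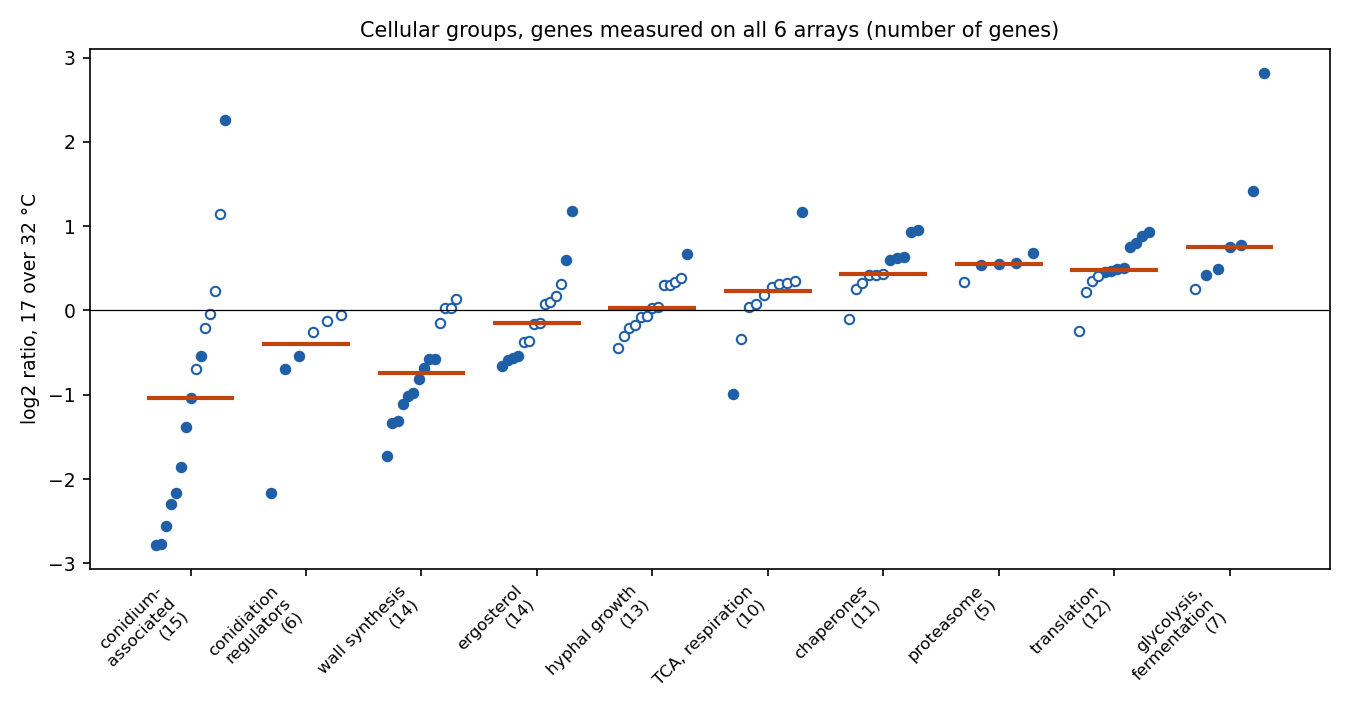
Log2 ratio of 17 over 32 °C (y axis) of genes measured on all 6 arrays, in 10 gene lists (x axis, number of genes in brackets). Points are means of 3 replicates, filled where the adjusted p is under 0.05, and lines are list medians. Medians run from -1.04 for conidium-associated genes to 0.75 for glycolysis and fermentation.

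Sterol synthesis genes moved in both directions. Of 14 ergosterol genes, 2 rose and 4 fell over all genes tested and adjusted over the list alone (camera adjusted p = 0.445). The early gene erg13A, for HMG-CoA synthase, stood at 1.18 ± 0.66, while erg6, a sterol methyltransferase gene, stood at -0.66 ± 0.05 and erg25B, a sterol oxidase gene, at -0.59 ± 0.08. Without replicate 2, 3 of the 6 calls remained, and without replicate 3, 4 did. The call of erg25B ended without replicate 2 (adjusted p = 0.0536), as did that of erg13, a riser at 0.60 (adjusted p = 0.212). The added list by symbol gave 2 of 15 higher and 4 lower (camera adjusted p = 0.563).

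Antioxidant genes by symbol had 3 of 10 members higher and 1 lower (camera adjusted p = 0.41). Of these 4 calls, 2 remained without replicate 2 and 2 without replicate 3. The glutathione reductase gene glr1 (0.43) then had adjusted p = 0.147 and 0.156. The superoxide dismutase gene sod2 stood at 0.98 ± 0.23 and the peroxiredoxin gene prx1 at -0.57 ± 0.30, which did not pass without replicate 2 (adjusted p = 0.114) or replicate 3 (0.113). The catalase gene of conidia, catA, stood in the larger set at -1.89 ± 0.54, and the planned antioxidant list had 2 of 7 higher and 1 lower, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.931). Of 13 genes of hyphal growth and the cytoskeleton, 1 rose (camera adjusted p = 0.632). It was the profilin gene pfy1 (0.67 ± 0.25), whose call ended without replicate 2 (adjusted p = 0.0626). The septin gene aspC stood at -0.44 ± 0.29 and sac6 at 0.38 ± 0.21, neither past the threshold.

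Proteases showed no shift as a list, with 1 of 7 higher and 2 lower (camera adjusted p = 0.745). Beside pep1, the aspartic protease gene ctsD stood at -0.81 ± 0.35 and the tripeptidyl peptidase gene sedD, saturated on 1 array, at -1.16 ± 0.94. Without replicate 1, sedD stood at -0.70, and without replicate 2 it had adjusted p = 0.0699. Of 5 drug efflux genes mfsC fell (camera adjusted p = 0.41), and abcB (0.20 ± 0.19) and atrF (-0.36 ± 0.44) did not pass. Of 5 siderophore and iron genes, sidL, an acetylase gene of siderophore synthesis, rose (0.74 ± 0.44, camera adjusted p = 0.41 for the list), and amcA (0.20 ± 0.14) and cccA (0.21 ± 0.25) did not pass. Among 16 peroxin genes of the larger set 3 fell, led by pex13 at -0.88 ± 0.19. Their camera adjusted p was 0.0209, with adjusted p = 0.563 with an estimated correlation and 0.0512 to 0.0695 when 1 replicate was left out. Of 18 ribosome biogenesis genes by symbol 1 was higher there, dim1 (camera adjusted p = 0.515), and of 5 on the planned list none passed in limma's test (camera adjusted p = 0.449). None of 9 mitochondrial import genes passed in limma's test (camera adjusted p = 0.968), and 1 of 14 DNA repair and replication genes was lower, slx4 (camera adjusted p = 0.846). Without replicate 2, dim1 had limma's adjusted p = 0.161 and slx4 0.148.

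A single gene was detected at 32 °C on 3 or more arrays and at 17 °C on none. AFUA_7G04540 passed the authors' filter at 32 °C on 1 array of each replicate and is listed at 0 at 17 °C on all 6 arrays. Because a spot that failed the filter holds 0 whatever its signal, no fold is given. There were 0 genes with the opposite pattern.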

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

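The count of probes without a listed gene and the values in the larger set were chosen as tests only after the result was seen. So was the refit without the array with the fewest measured spots. The other tests in this part were planned. Probes that the probe table does not list were left out of the comparison, and 116 pairs of them were measured on all 6 arrays. In the same limma test 37 of these pairs passed the threshold, 17 higher and 20 lower at 17 °C, which is 31.9%. Among listed genes fitted together with them, 35.5% passed. What these probes represent is not known from the files, and no explanation was tested.

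For the 631 genes that differed, dye effects and the array with the fewest measured spots were weighed. The called genes had the same sign in both dye orientations in 99.5% of cases, 628 of 631. They were called on means of swapped arrays, in which the dye effect cancels, so this share could hardly have been low. It shows only that the dye effect was smaller than the change in nearly all called genes. Over the other 5 arrays their median size was 99.6% of that over all 6. This share too could hardly have been low, because the genes were called on all 6 arrays and that weak array is a small part of each mean. It therefore does not decide whether the weak array was the cause. A refit without the weak array still called 572 of the 631 genes, so most calls did not need it. Turning the sign of whole replicates gives 4 patterns, of which the real one called 631 genes and the highest other 0, and 4 patterns are too few for a share under 0.05. Temperature itself stays open as the explanation, as do other differences between the plates, such as growth stage after 48 h, for which the design has no test.

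Genes associated with conidia were mostly lower at 17 °C, and a different share of conidia in the harvests was weighed. Of the 15 tested members 80% lay below 0, with a median of -1.04, and in the larger set 77.8% of 18 did, with a median of -1.21. Without replicate 1 these medians were -0.60 and -0.69. The share lies at the bound of 80% set beforehand and on either side of it in the 2 sets, and dprB rose. Fewer conidia at 17 °C may therefore account for part of the pattern, and this cannot be told apart from lower expression within the same conidia, because every array compares a whole culture at one temperature with a whole culture at the other.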

How the results depend on the processing

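The alternatives that change the gene numbering, use genes with 1 array per replicate, or leave out the weak array were chosen as tests only after the result was seen. Of the 1757 genes, median centring called 617, loess within print tips 566 of 1719, normexp 595, a dye coefficient 656, and a fit with trend and robust variance 776. Counts moved by over 1.5 times in settings that test other genes. They were 1138 with at least 1 array in each replicate, 1108 with at least 1 array in at least 2 replicates, 1184 with only the arrays that have 17 °C in Cy3, 1089 without the weak array and 1331 in the authors' value table. Using fewer arrays or the authors' value table also changes the values. Counts also moved in stricter tests, to 141 against a 1.5-fold change, 136 without the replicate block and 1 in the ordinary one-sample test, which does not share the spread between genes. Without replicate 2 the number was 400, also a move of over 1.5 times, and without replicate 1 or 3 it was 636 or 524. Averaging spots by the median, which can differ from the mean only for the 10 genes with 4 spots, called 631. Scaling between arrays moves no ratio by construction. Under the deposited numbering 669 of 2397 genes were called, of which 66 were shared with the 631 and 29 of those had the opposite sign. No gene shared with the 631 had the opposite sign in any other setting. A filter-free setting could not be run. The replicate 3 array with 17 °C in Cy5 had the fewest spots measured in both channels, 16.8%, and the cause was not tested. With the spots of lowest background-corrected signal in either channel left out, 442 of 1146 genes were called.

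Of 6 planned lists 4 passed, against 8 of 14 in the authors' value table and 8 of 14 with at least 1 array in each replicate, where more lists reach 5 genes. The number was 0 with an estimated correlation, 2 with fry, 0 under the deposited numbering, and 3 to 4 with 1 replicate left out. Of the 13 added lists 6 passed, against 1 with fry and 0 with an estimated correlation. Of 78 named genes 64 passed, against 35 of 47 with dim spots left out, 36 without the replicate block, 0 in the ordinary one-sample test, 11 of 24 under the deposited numbering, and 54 to 66 with 1 replicate left out. Of the 78, 74 kept their sign in every setting run other than the deposited numbering, under which 16 of 24 did, and 67 kept it with that setting included. Named genes other than the allergens were chosen for a large change or a low p in these same data. How many passed and kept their sign was thus partly set by that choice.

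Some list medians and single genes changed sign, and the cause was not tested apart from the numbering. Under the deposited numbering these included large changes, such as mp2 at -3.31 and AFUA_4G01360 at 3.17 in the test of all 3 replicates. Under that numbering list medians were 0.0712 for conidiation regulators, 0.119 for ergosterol synthesis, 0.115 for its list by symbol, -0.217 for chaperones, 0.0224 for wall synthases, -0.142 for translation, -0.0548 for siderophores, -0.132 for the TCA cycle and 0.0475 for conidium-associated genes. Of single genes, chsA then stood at 1.40 and sod2 at -1.44, both past the threshold, and mp2 at 0.33, dmaW at 0.14, rodC at 0.05, AFUA_4G01360 at -0.0203, hsp90 at -0.22 and abcB at -0.50, none of them past it. The protease list's median was -0.0326 in the authors' value table, -0.00111 with at least 1 array in each replicate and -0.134 without the weak array. For drug efflux it was 0.0596 in the authors' table and 0.0294 without the weak array. For hyphal growth it was -0.0540 to 0.0851 with 1 replicate left out and -0.0251 without the weak array. With only the arrays that have 17 °C in Cy3, cccA stood at -0.114 and abcB at -0.0577. With only those that have 32 °C in Cy3, aspf2 stood at -0.256 and alp2 at 0.101. Leaving out 1 replicate gave aspf2 -0.0357 to 0.0773 and alp2 -0.207 to 0.190. The value of alp2 was also 0.0704 after median centring, 0.132 with print-tip loess, 0.112 with no normalization, 0.00755 with dim spots left out, 0.187 in the authors' value table and 0.0162 without the weak array. The genes cccA, abcB, aspf2 and alp2 did not pass the threshold in the test of all 3 replicates.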

Other observations

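The genes in this first paragraph, the tests that leave out the cluster lists or split by direction, and those in the larger set were chosen only after the result was seen. The genes were picked one by one for their values, and no group of them was tested. Lower at 17 °C in the larger set were facB, a regulator of acetate use (-1.08 ± 0.32), facA, for acetyl-CoA synthetase (-0.94 ± 0.28), and acuF, for phosphoenolpyruvate carboxykinase (-1.75 ± 0.78), beside acuE at -0.99 ± 0.06. So were chi3, a chitinase gene (-2.29 ± 0.71), eng2, an endoglucanase gene (-1.56 ± 0.18), and exg12, a glucanase gene (-1.46 ± 0.35). Also lower were nce102 (-1.39 ± 0.13) and pil1 (-1.10 ± 0.45), whose products belong to the eisosome, a membrane domain. The ferric reductase gene fre7 was higher at 1.49 ± 0.39. All these values are means of n = 3 with limma's adjusted p between 0.000252 for eng2 and 0.00382 for pil1.

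Called genes lay beside each other on chromosomes more often than shuffled calls did. Of 373 pairs of neighbouring tested genes, 45 were both called in the same direction, against a mean of 23.7 and at most 39 in 1000 shuffles. Among the 364 pairs whose spots lie in different print blocks the observed number was 1.90 times the shuffled mean. Nearly all pairs are of this kind, so the ratio could hardly differ from that of all pairs, also 1.90. These values argue against a shared print block as the source of the excess. Closeness on the slide across blocks was not tested. Without the cluster lists 33 pairs remained against 22.2, above 99.1% of shuffles. In the larger set 107 of 2752 pairs compared with a mean of 73.0, and without the cluster lists 82 with 68.3, which lies within the middle 95% of shuffles (54 to 83). Whether neighbours outside these clusters add to the pattern is thus left open. The correlation of neighbours was also used to settle which spot holds which gene, so this test is not independent of that choice.

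The longest runs of genes called in one direction, among those tested in the larger set, lay in the clusters already described. From AFUA_8G00470 to AFUA_8G00580, 10 genes were higher with a median of 1.39, and from AFUA_8G00370 to AFUA_8G00440, 8 were higher with a median of 1.45. From AFUA_6G03400 to AFUA_6G03460, 5 fumipyrrole genes or neighbours were higher with a median of 2.20. Lower runs of 4 genes lay from AFUA_1G05745 to AFUA_1G05800, with exg12 and the kinase gene mkk2 (median -1.04), and from AFUA_3G12670 to AFUA_3G12720, with glfB (median -0.76).

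A further hypothesis was that genes near chromosome ends changed more often. Among the 50 genes nearest each end, 40 of 85 tested genes were called, against 591 of 1672 elsewhere, an odds ratio of 1.63 (95% interval 1.02 to 2.58, two-sided Fisher's exact p = 0.0364), which missed the bound of 0.01 set beforehand. Split by direction, it was 2.37 for genes higher at 17 °C (Fisher's exact p = 0.000607) and 0.772 for genes lower there (Fisher's exact p = 0.477), and the difference between directions was not tested. The larger set gave an odds ratio of 2.15 (Fisher's exact p = 2.12e-07), with 2.68 for higher genes (Fisher's exact p = 3.41e-08) and 1.24 for lower ones (Fisher's exact p = 0.291). Without the cluster lists it was 1.04 (Fisher's exact p = 0.892), and 1.59 in the larger set (Fisher's exact p = 0.00611). The clusters near the ends could thus carry much of the excess, and whether other genes near the ends add to it is left open by these values. Fisher's test takes each gene as independent, but called genes lay beside each other more often than shuffled calls did. The Fisher p-values are therefore likely too small.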
